A study of Marchantia polymorpha subsp. ruderalis with 24 samples.

How the data were processed

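Messenger RNA was measured in young thallus of the liverwort Marchantia polymorpha subsp. ruderalis, whose main plant body is a flat haploid thallus. The strain was Takaragaike-1 (Tak-1), a male laboratory accession. Per the labels' protocols, plants were raised from gemmae (clonal propagules formed in cups on the thallus) on agar under cycles of 12 h light and 12 h dark at 20 °C, with 50 to 60 µmol photons per square metre and second. They were then moved to constant light. Tissue was collected every 6 h from 24 h to 66 h after the move, with 3 replicates at each of 8 times, which gave 24 libraries. Per the labels, the RNA was taken up on a column with DNase digestion, and stranded TruSeq libraries with poly(A) selection were made from 100 ng of total RNA. The labels do not say at which hour of the light-dark cycle the plants were moved, so phases are given in hours after the move, modulo 24 h. The labels also do not say whether the replicates were separate cultures. The p-values then measure only the spread between these samples, which may be technical.

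The deposited table holds whole-number counts per gene, made by the authors and not normalized. It has 20574 genes and 1 column for each of the 24 libraries. The aligner, the counting program, its strand setting and the genome build are not given in the sources used here. Overlapping genes, genes on opposite strands of one stretch of DNA, and members of gene families with near-identical copies can therefore share reads, and values of such genes are uncertain. Library totals ranged from 14929708 to 59194999 counts.

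The table gives gene identifiers without names. Names came from a RefSeq gene table of assembly MpTak2_v7.1, joined on the locus tag, and no coordinate of that assembly was used. Of the identifiers, 17641 matched an entry and 3091 carried a symbol. Among the tested genes 2572 had a symbol. The join was checked by co-expression. The median correlation between members was 0.848 among MCM2 to MCM7, 0.742 among the core histones and 0.900 among the HSP90 genes, against 0.007, 0.026 and 0.003 for the genes after them in identifier order and 0.229, 0.082 and −0.192 for the genes before them. The identifiers carry the suffix of another annotation version than the names, and the join rests on their digits alone. Outside these 3 sets a gene that was renumbered between versions would carry a wrong symbol.

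Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the times as groups and a minimum count of 10, which left 14414 genes and set aside 6160. Libraries were scaled by TMM, with factors from 0.932 to 1.10. Quasi-likelihood F-tests (glmQLFit and glmQLFTest) were used throughout, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The 24 h rhythm was tested with the cosine and sine of a 24 h period together, beside a linear term in hours. The size of a rhythm is the fitted difference between peak and trough on the log2 scale, and its fold is that difference as a ratio. A model with 1 mean per time gave the test of any difference between times, the difference between the days (mean of 48, 54, 60 and 66 h minus mean of 24, 30, 36 and 42 h), 4 contrasts of times 24 h apart and 4 contrasts of times 12 h apart. Whether the rhythm differed between the days was tested with day-by-cosine and day-by-sine terms, beside a day term and without a linear term. Swings and peaks of a single day were taken from the 4 time means of log2 CPM of that day, without a drift term. They are thus another measure than the fitted rhythm, and a drift within a day enters them. Errors of fitted values are standard errors (SE), and errors of CPM (counts divided by library size and TMM factor, as given by edgeR's cpm function) are standard deviations (SD) over the 3 replicates of a time.

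Gene lists were matched by symbol. Of 25 lists, 16 had at least 3 tested members, and 7 had no member with a symbol: SHAQKYF-type MYB, GARP MYB-related, CCT domain, light harvesting, photosystem subunits, starch metabolism and cytosolic ribosomal proteins. Nothing is reported for those 7. The rhizoid list and the list for sexual organs and sperm had fewer than 3 tested members and are given as values. Rhythm calls in a list were set against those in the other tested genes with a two-sided Fisher's exact test, which takes genes as independent. Day changes of a list were tested with camera of limma 3.58.1, which compares the members with all other genes, at a preset correlation of 0.01 and again with the correlation estimated from the data. Both were adjusted over the 16 lists. Named genes were every tested member of the lists for the core clock, for DET1, COP1 and HY5 light signalling and for photoreceptors; the 10 genes called rhythmic with a symbol, a mean CPM of 10 or more and a correlation between the profiles of the days of 0.8 or more that had the largest fitted rhythm; the 5 largest rises and 5 largest falls between the days among genes called for that change with a symbol, a mean CPM of 10 or more and one sign in all 4 same-phase contrasts; and 2 to 4 members of each other list with the smallest p for the rhythm, with at most 2 for the day change. A few symbols caught by a list's pattern that stand for other proteins, such as glycosyl hydrolases under GH3, were removed before testing, and 1 auxin gene whose symbol was doubtful is not named.

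The groups, tests, gene lists, naming rule and the alternatives below were chosen before the data were examined. These alternatives were DESeq2's size factors in edgeR, every gene with any count, a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, periods of 22, 26 and 28 h, no drift term or 1 mean per day in place of the linear term, a rhythm of at least 1.5 fold, and a rank test with cosine templates. For pairs of times, a fit of those times alone was added. Chosen after seeing the data were a rhythm fit with linear and day terms together, fits without the 3 libraries in which the gene MpVg01240 took over 4% of the counts, and fits with the main axis of variation within times as a covariate. Grouping genes by the stem of their symbol was also chosen after seeing the data.

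The tests were tested on simulated data, with counts drawn for the 14414 genes from the means, spread and library sizes of these data, 200 genes given a rhythm and 200 others a step between the days. Of simulated 24 h rhythms the rhythm test found 67.2% at 1.5 fold, 67.2% at 2 fold and 93.9% at 4 fold, and the rank test found 31.3%, 47.8% and 77.3%. The median error of the fitted peak was 0.254 h. Of 198 genes that the rhythm test called, 40 carried no rhythm but a simulated step between the days and 6 were unchanged. The linear term thus takes up a step between days only in part. The day contrast found 52.2% of simulated changes of 1.25 fold, 82.1% at 1.5 fold and 87.9% at 2 fold.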

Results

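The series followed messenger RNA in wild-type young thallus of Marchantia polymorpha through 2 days of constant light. Plants that had grown in 12 h light and 12 h dark were moved to constant light and sampled every 6 h from 24 to 66 h after the move. There were 3 libraries at each of 8 times. With the light-dark cycle removed, a daily rhythm that remains comes from within the plant. The title names DE-ETIOLATED1 (DET1) as the gene of interest in this clock. The 24 libraries held 14929708 counts (replicate 2 of 66 h) to 59194999 counts (replicate 1 of 66 h). Libraries of the same time correlated at 0.956 to 0.989 across genes, and no pair differed as little as counting noise allows (chi-square per degree of freedom 11.7 to 166). Time accounted for 46.7% of the variance between libraries. Random groups of 3 libraries would also take up a part of the variance, and that part was not subtracted. A single gene, MpVg01240, took 7.22% of the counts in replicate 3 of 24 h, 4.44% in replicate 3 of 30 h and 4.27% in replicate 3 of 66 h, and 0.301% to 2.39% elsewhere. This gene was chosen after its values were seen.

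A large part of the transcriptome had a 24 h rhythm. The rhythm test called 2700 of 14414 genes (18.7%) at an edgeR adjusted p under 0.05. The median change of these genes between trough and peak was 1.47 fold, with 471 genes at 2 fold or more and 78 at 4 fold or more. Among genes called rhythmic with a symbol, a mean of 10 CPM or more and like profiles on both days, the widest swings were those of MpPPR_73 (Mp8g16250), a pentatricopeptide repeat protein gene, at 2.79 ± 0.25 (SE) on the log2 scale, and of the B-box gene MpBBX1 at 2.68 ± 0.27. Next came those of the dirigent gene MpDIR27 (Mp5g00590) at 2.62 ± 0.33 and of the pseudo-response regulator gene MpPRR at 2.39 ± 0.17. The rest of the 10 were MpKOL3 (Mp2g01940, 4.29 fold), the lipoxygenase gene MpLOX14 (Mp8g12930, 1.94 ± 0.23) and the protein phosphatase gene MpPP2C_F3 (Mp4g14730, 1.85 ± 0.27). They also included the receptor kinase gene MpRLK-Pelle_LysM3 (Mp6g15550, 1.72 ± 0.15), the Dof transcription factor gene MpCDF (Mp1g18540, 1.62 ± 0.13) and MpEXL3 (Mp7g19240, 1.56 ± 0.14). Their adjusted p ranged from 8.9e-05 for MpPP2C_F3 to 9.3e-10 for MpPRR. The call was sensitive to how a change between the days was modelled. With a linear term and a day term together 1009 genes were called, 995 of them among the 2700. MpDIR27 (adjusted p = 0.0929) and MpLOX14 (adjusted p = 0.0744) were then lost. A day term alone gave 4269 genes, a rank test 1460 and a 22 h period 1712.

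Of the core clock genes, MpPRR cycled by far the most. MpPRR (Mp2g16560) encodes a pseudo-response regulator, a class of repressors in plant clocks. Its level rose from 66.1 ± 5.1 CPM (SD, n = 3) at 24 h to 274 ± 33 at 30 h, fell to 60.5 ± 3.6 at 42 h and rose again to 265 ± 52 at 60 h. All 12 libraries of 30, 36, 54 and 60 h, with at least 199 CPM of MpPRR, lay above all 12 of the other times, with at most 125 CPM. The fitted rhythm of MpPRR was 5.25 fold, with a peak at 9.07 ± 0.27 h (edgeR adjusted p = 9.3e-10). The other rhythmic members changed little. MpTOC1 (Mp3g09460), another pseudo-response regulator gene, changed by 0.44 ± 0.10 with a peak at 13.3 h (adjusted p = 0.0068). The REVEILLE-type MYB gene Mp1R-MYB11 (Mp2g14310) changed by 1.31 fold with a peak at 9.64 h (adjusted p = 0.0191) and MpGI (Mp1g13750), the GIGANTEA homologue, by 1.17 fold with a peak at 13.1 h (adjusted p = 0.0209). No rhythm was called for MpELF3 (0.14 ± 0.09, adjusted p = 0.551), MpELF4 (0.01 ± 0.10, adjusted p = 0.998), MpFKF (0.18 ± 0.06, adjusted p = 0.101) or the LUX homologue MpGARP7 (0.17 ± 0.08, adjusted p = 0.347). MpGARP7 was called with day means in place of the linear drift (adjusted p = 0.00183) but not with both terms (adjusted p = 0.490), and MpFKF without replicate 2 of 60 h (adjusted p = 0.0479). In all, 4 of the 8 tested clock genes were rhythmic, and 5 adjusted over the list alone. The share was not above that of the other genes after adjustment (Fisher's exact test, odds ratio 4.34, adjusted p = 0.130, but 0.0463 without replicate 2 of 60 h). The linear and day terms together left MpTOC1 (adjusted p = 0.243) and MpGI (adjusted p = 0.192) uncalled. Mp1R-MYB11 was uncalled without the 3 libraries rich in MpVg01240 (adjusted p = 0.0545) and MpGI without replicate 1 of 36 h (adjusted p = 0.0686).

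The light signalling gene named in the title cycled as well. MpDET1 (Mp8g00970) encodes the homologue of DET1, which in flowering plants works with DDB1 and COP10 to hold back light responses in the dark. Its level was 137 ± 5.5 CPM (SD, n = 3) at 24 h, 46.8 ± 1.9 at 36 h, 129 ± 15 at 48 h and 60.9 ± 9.2 at 66 h. Each of the 6 libraries of 24 and 48 h had at least 117 CPM of MpDET1 while none of the 12 of 36, 42, 60 and 66 h had over 74.8. The fitted rhythm of MpDET1 was 2.73 fold (log2 1.45 ± 0.12) with a peak at 1.86 ± 0.32 h (edgeR adjusted p = 5.7e-08), about 7 h before that of MpPRR. MpBBX1 (Mp5g05940) changed by 6.40 fold with a peak at 6.25 ± 0.36 h (adjusted p = 2.0e-07), from 9.59 CPM at 42 h to 90.0 CPM at 30 h. MpBBX6 (Mp2g16350) changed by 2.46 fold with a peak at 14.8 h (adjusted p = 5.2e-06), and the phytochrome-interacting factor gene MpBHLH6 (Mp3g17350) by 1.48 fold with a peak at 9.85 h (adjusted p = 0.0025). MpCOP1 (Mp5g12010), a ubiquitin ligase gene, changed by 1.39 fold with a peak at 3.85 h (adjusted p = 5.5e-04). The other members were not called: MpDDB1, MpCOP10, MpSPA1 (adjusted p = 0.0895), MpRUP, MpBBX2, MpBBX3 (adjusted p = 0.0826), MpBBX4 and MpBBX5. MpBBX3 gained a call with day means as drift (adjusted p = 0.0174), MpSPA1 with DESeq2 (adjusted p = 0.0457) and MpBBX2 with limma-voom (adjusted p = 0.0427). Among the 4 photoreceptor genes the blue-light receptor gene MpPHOT (Mp5g03810) was called, at 1.42 fold with a peak at 3.97 h (adjusted p = 2.8e-04). MpPHY (adjusted p = 0.0579), MpCRY and MpUVR8 were not called, but MpPHY was called on leaving out 5 of the 24 single libraries and in 5 other settings, among them day means as drift (adjusted p = 0.0294) and DESeq2 (adjusted p = 0.0255). The light signalling list had 5 of 13 members rhythmic (8 adjusted over the list alone, Fisher's exact test adjusted p = 0.179) and the photoreceptor list 1 of 4 (2 adjusted over the list alone, adjusted p = 0.752). With linear and day terms together MpCOP1 (adjusted p = 0.603) and MpPHOT (adjusted p = 0.199) were not called. The calls of MpDET1 (adjusted p = 0.0028), MpBBX1 (adjusted p = 2.9e-06), MpBBX6 (adjusted p = 0.026) and MpPRR (adjusted p = 2.7e-09) held.

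**Figure D1:**
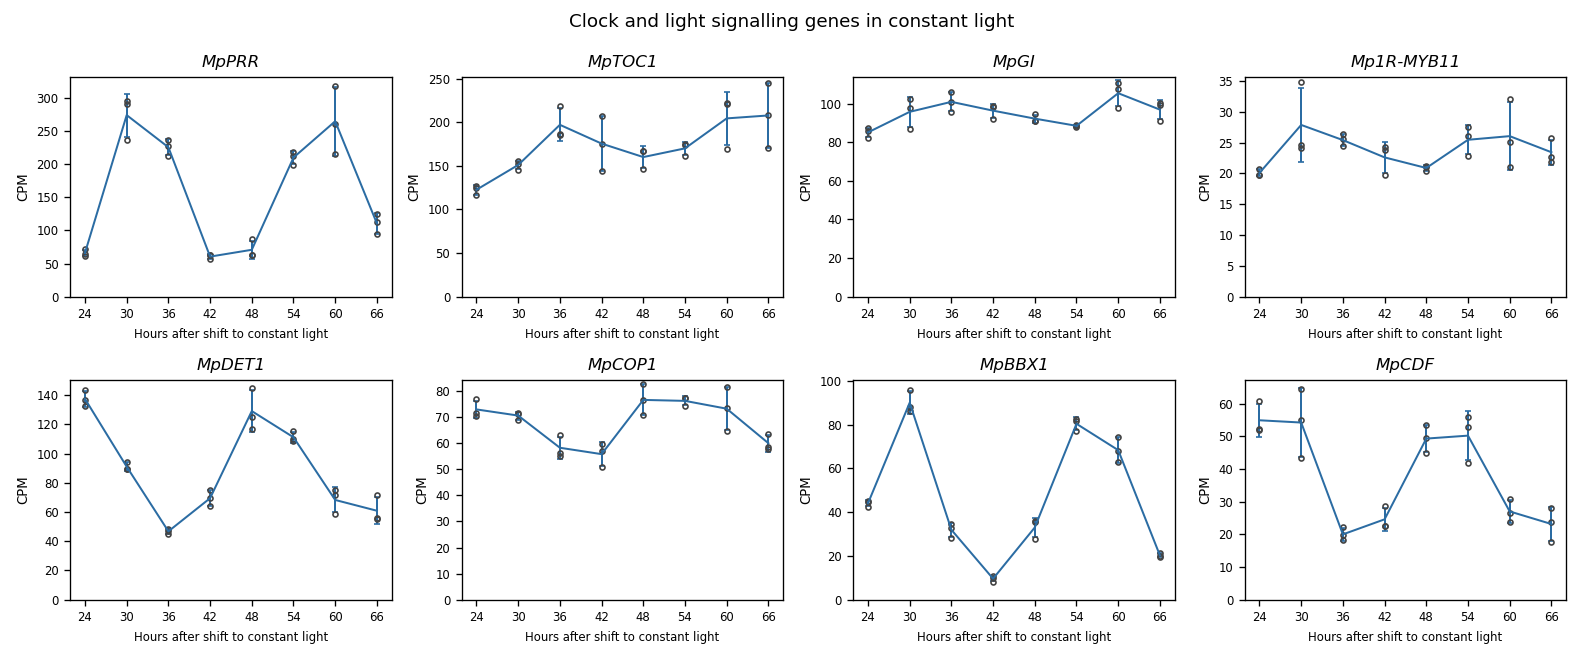
Level of 8 clock, light signalling and related genes in CPM against hours after the move to constant light. Open points are the 3 libraries of a time, and the line joins their means with bars of 1 SD; MpPRR swings between 60.5 and 274 CPM and MpDET1 between 46.8 and 137 CPM, with MpDET1 high at 24 and 48 h.

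Genes of phenylpropanoid and flavonoid synthesis, which make phenolic compounds from phenylalanine, were rhythmic more often than other genes. Of 36 tested members 17 were called (23 adjusted over the list alone), with an odds ratio of 3.90 (Fisher's exact test, adjusted p = 0.00147). The test takes genes as independent, but the members varied together (correlation estimated by camera 0.157), so its p may be too small. Leaving out single libraries gave an adjusted p from 6.6e-05 to 0.0486, the highest without replicate 1 of 42 h. Of the 17, 11 peaked within 3 h of 0 h. MpPKS/CHS15 (Mp4g14200) and MpPKS/CHS14 (Mp4g14190), genes of the chalcone synthase family with neighbouring identifiers that may share reads, changed by 2.05 and 1.80 fold with peaks at 0.366 h and 0.802 h. MpPAL10 (Mp1g05190), a phenylalanine ammonia-lyase gene, changed by 1.34 fold with a peak at 23.0 h, while MpPKS/CHS5 (Mp2g22690) peaked at 12.7 h with 1.59 fold and MpPKS/CHS20 (Mp7g14890) at 4.78 h with 1.85 fold. The call for MpPKS/CHS20 was lost with linear and day terms together (adjusted p = 0.0681) and that for MpPAL10 without a drift term (adjusted p = 0.0877).

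Small sets of chloroplast and hormone genes had rhythmic members without a list-wide call. All 3 tested genes of tetrapyrrole synthesis, the route to chlorophyll, were rhythmic (3 adjusted over the list alone, Fisher's exact test adjusted p = 0.0525). They were MpCHLD (Mp6g04260) with 1.44 fold and a peak at 10.6 h, MpGUN4 (Mp6g06740) with 1.51 fold and a peak at 4.27 h, and MpCHLI1/2-like (Mp2g21150) with 1.31 fold and a peak at 7.71 h. That list passed the threshold in several other settings, with an adjusted p of 0.0139 when rhythm calls were taken at an adjusted p under 0.01 and of 0.0319 to 0.0581 on leaving out single libraries, under the threshold in 19 of 24 cases. In the Calvin cycle list 3 of 5 genes were called (3 adjusted over the list alone, adjusted p = 0.130). These were the aldolase genes MpFBA2 (Mp6g07690, 1.45 fold, peak at 1.87 h), MpFBA4 (Mp2g02260, 1.34 fold, peak at 6.38 h) and MpFBA3 (Mp2g04730, peak at 20.6 h). The auxin list had 6 of 14 called (7 adjusted over the list alone, adjusted p = 0.130, but 0.0422 without replicate 2 of 48 h). Among them were MpGH3A (Mp6g07600, 1.56 fold, peak at 4.52 h), which conjugates auxin, and MpTAA (Mp5g14320, 1.59 fold, peak at 11.4 h) of auxin synthesis. Others were the auxin efflux gene MpPIN1 (Mp3g21660, 1.34 fold, peak at 15.1 h) and the co-repressor gene MpTPL (Mp7g17410, 1.17 fold, peak at 20.8 h). With linear and day terms together MpGUN4 (adjusted p = 0.262), MpFBA2 (adjusted p = 0.302), MpFBA4 (adjusted p = 0.0616), MpFBA3 (adjusted p = 0.0762), MpGH3A (adjusted p = 0.0828) and MpPIN1 (adjusted p = 0.336) were not called. The call of MpFBA3 was also lost on leaving out 7 of the 24 single libraries.

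No member of the cell cycle list (0 of 13, 0 adjusted over the list alone, Fisher's exact test adjusted p = 0.292) or of the core histone list (0 of 24, 0 adjusted over the list alone, adjusted p = 0.0786) was called rhythmic by edgeR with a linear drift, nor by DESeq2 or limma-voom. At an unadjusted p under 0.05 edgeR gave 0 cell cycle and 2 histone genes, DESeq2 0 and 3, and limma-voom 0 and 2. The values nearest to a call there were 0.32 ± 0.09 for MpH4e (Mp5g16840, adjusted p = 0.0663), 0.27 ± 0.08 for MpH2B.1 (Mp7g18140, adjusted p = 0.0732) and 0.24 ± 0.10 for MpH2B.2 (Mp7g05430, adjusted p = 0.202). With day means in place of the linear drift MpH2B.1 (adjusted p = 1.0e-04), MpH4e (adjusted p = 0.0134) and MpCYCD_2 (adjusted p = 0.0366) were called, and with both terms none of these 3 (adjusted p = 0.750, 0.906 and 0.521). MpH4e also gained a call on leaving out 5 of the 24 single libraries and MpH2B.1 on leaving out 2, and both were called without the 3 libraries rich in MpVg01240 (adjusted p = 0.0165 each). Of the class III peroxidases, secreted enzymes of the cell wall, 17 of 119 were called (9 adjusted over the list alone, adjusted p = 0.425). They included MpPOD169 (Mp8g16260, 7.45 fold, peak at 1.90 h), MpPOD144 (Mp7g05770, 1.97 fold, peak at 12.2 h), MpPOD26 (Mp3g15330, 2.56 fold, peak at 13.2 h) and MpPOD23 (Mp3g06650, 1.60 fold, peak at 12.4 h). MpPOD169 and MpPPR_73 have neighbouring identifiers and similar profiles, so reads of the stronger gene may have been counted for the weaker one. Of R2R3-MYB genes 4 of 16 were called (4 adjusted over the list alone, adjusted p = 0.752). The peaks of MpR2R3-MYB5 (Mp8g11870, 1.86 fold), MpR2R3-MYB17 (Mp1g09420, 1.57 fold), MpR2R3-MYB14 (Mp5g19050, 5.91 fold at a mean of 0.690 CPM) and MpR2R3-MYB15 (Mp3g09350, 1.64 fold) lay between 20.2 h and 1.00 h. The AP2/ERF list had 2 of 14 (2 adjusted over the list alone, adjusted p = 1.00), MpERF2 (Mp7g13760, 1.71 fold, peak at 16.9 h) and MpERF18 (Mp5g12480, 1.86 fold, peak at 9.53 h). The heat shock list had 1 of 5 (1 adjusted over the list alone, adjusted p = 1.00), MpHSP90-1 (Mp1g26610, log2 0.44). The list of reference genes had 1 of 7 (2 adjusted over the list alone, adjusted p = 1.00), the tubulin gene MpTUB2 (Mp2g09390, 1.39 fold). With linear and day terms together MpPOD26 (adjusted p = 0.0538), MpERF2 (adjusted p = 0.0868) and MpHSP90-1 (adjusted p = 0.485) were not called, and the call of MpHSP90-1 was also lost on leaving out 3 of the 24 single libraries.

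In the main fit, rhythmic genes peaked at all phases but gathered around a pair of phases about 12 h apart. Within 3 h of 0 h lay the peaks of 890 genes, including MpDET1, MpPPR_73, MpDIR27 and MpCDF (2.95 h). Within 3 h of 12 h lay those of 946 genes, including MpTOC1, MpGI, MpKOL3 (12.4 h), MpEXL3 (12.5 h) and MpRLK-Pelle_LysM3 (11.2 h). The sectors around 6 h, with MpBBX1, and around 18 h, with MpPP2C_F3 (15.3 h), held 504 and 360 genes. By the hour, the peaks had local maxima from 2 to 3 h (233 genes, with 230 in the hour before) and from 13 to 14 h (211 genes). Of these, 63 of the 233 reached 2 fold or more against 27 of the 211. A fit with linear and day terms together left 275, 197, 419 and 118 genes in the sectors around 0, 6, 12 and 18 h, and a day term alone 1471 around 12 h and 843 around 18 h. Rhythm calls and calls between the days shared 1236 genes, against 934 if independent. The linear term takes up a step between the days only in part, so such steps may add to the counts of the main fit. By the design of that fit, a rising step adds a peak midway between 0 and 6 h. A falling step adds one midway between 12 and 18 h. These places lie near the local maxima, so the maxima cannot be read as phases of a rhythm alone. How much such steps add to each sector was not tested.

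**Figure D2:**
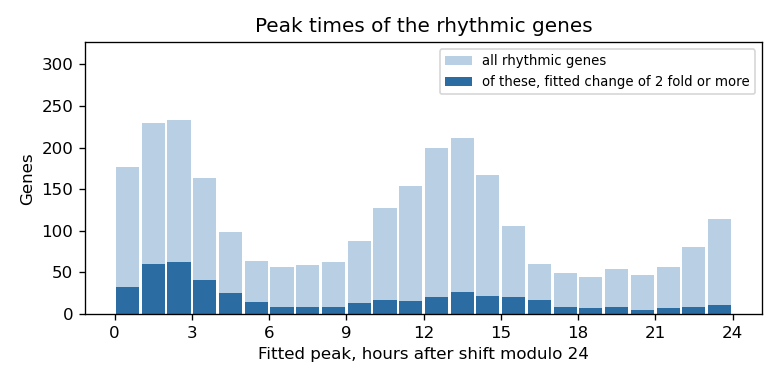
Number of rhythmic genes by the hour of their fitted peak, in hours after the move modulo 24. Light bars count all 2700 rhythmic genes and dark bars those of 2 fold or more; both gather at 0 to 4 h, and the light bars again at 11 to 15 h.

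Direct comparison of times without an assumed shape gave more genes. Some difference between the 8 times was called for 5307 genes (36.8%, edgeR adjusted p under 0.05), of which 2367 were also rhythmic. Times 12 h apart, opposite phases of a 24 h cycle, differed in 2828 genes for 36 against 24 h (1501 higher and 1327 lower at the later time) and in 1695 for 42 against 30 h (796 and 899). They differed in 1046 for 60 against 48 h (626 and 420) and in 976 for 66 against 54 h (311 and 665). Rhythmic genes made up 1846, 934, 897 and 726 of these. The counts rest on few libraries. The 42 against 30 h contrast had 941 genes without replicate 3 of 30 h and 994 without replicate 2 of 42 h. The 60 against 48 h contrast had 614 without replicate 3 of 48 h and 580 without replicate 1 of 60 h. The 66 against 54 h contrast had 640 without replicate 1 of 54 h, 506 without replicate 3 of 54 h and 602 without replicate 1 of 66 h. Fitting the pair of times alone gave 879, 450 and 402 genes for these 3 contrasts, but 3520 for 36 against 24 h.

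Between the first and the second day sampled, with each phase represented in both, 4988 genes (34.6%) differed in mean level, 2639 upward and 2349 downward. Most changes were small: 486 rose and 271 fell by at least 1.5 fold, and 200 and 48 by at least 2 fold. Among called genes with a symbol, a mean of 10 CPM or more and one direction at all 4 phases, the largest rises were in dirigent genes, whose products guide the coupling of phenolic radicals. MpDIR45 (Mp3g24170) rose by 3.05 ± 0.67 on the log2 scale (edgeR adjusted p = 0.0013) and MpDIR64 (Mp3g24210) by 2.76 ± 0.64, followed by MpDIR47 (Mp3g24150) by 1.80 ± 0.42, MpDIR46 (Mp3g24160) by 1.75 ± 0.39 and MpDIR48 (Mp3g24140) by 1.74 ± 0.39. These 5 have neighbouring identifiers and may share reads, and they varied widely within times: MpDIR45 was at 51.2, 0.473 and 5.08 CPM in the 3 libraries of 48 h. The same libraries had 26.03, 3.41 and 5.83 CPM of the gemma cup gene MpGCAM1. At 54 h MpDIR45 was at 20.8, 53.9 and 1.95 CPM and MpGCAM1 at 11.4, 22.9 and 4.82 CPM. With limma-voom MpDIR45 (adjusted p = 0.0825) and MpDIR64 (adjusted p = 0.0733) were not called. Within the same limits the largest falls were in the peroxidase genes MpPOD99 (Mp5g13710), which fell by 1.17 ± 0.09, and MpPOD63 (Mp5g02840), which fell by 1.17 ± 0.12. Next were MpPOD98 (Mp5g13650), which fell by 0.84 ± 0.15, and MpPOD118 (Mp5g17140), which fell by 0.78 ± 0.09. MpHA5 (Mp3g12380), a plasma membrane proton pump gene, fell by 1.00 ± 0.10 (adjusted p = 5.8e-07). At the same phase MpHA5 went from 72.2 ± 4.0 CPM (SD, n = 3) at 24 h to 34.6 ± 5.3 at 48 h and from 41.5 ± 4.6 at 42 h to 21.95 ± 4.81 at 66 h.

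Some clock and light signalling genes rose slightly between the days, without a call for either list. Of the 8 clock genes 4 rose and none of the 8 fell (4 adjusted over the list alone). MpPRR and MpTOC1 rose by 0.21 ± 0.07 each (edgeR adjusted p = 0.0245 and 0.0149), MpELF4 by 0.23 ± 0.07 (adjusted p = 0.014) and MpGARP7 by 0.29 ± 0.05 (adjusted p = 1.1e-04). Of the 13 light signalling genes 6 rose and 1 fell (7 adjusted over the list alone). MpBBX1 rose by 0.40 ± 0.05 (adjusted p = 7.7e-06), MpBHLH6 by 0.27 ± 0.08, MpBBX5 by 0.21 ± 0.06, MpCOP10 by 0.20 ± 0.08, MpCOP1 by 0.15 ± 0.04 and MpDET1 by 0.14 ± 0.05 (adjusted p = 0.0422). MpDDB1 fell by 0.10 ± 0.04 (adjusted p = 0.0399). Neither list stood apart from the other genes (camera adjusted p = 0.110 for both, and 0.851 for both with an estimated correlation), although both passed without replicate 3 of 60 h (adjusted p = 0.0285 and 0.0252). No photoreceptor gene was called by edgeR, nor by DESeq2 or limma-voom or at an unadjusted p under 0.05 (0 of 4, 0 adjusted over the list alone, camera adjusted p = 0.799). The calls for MpDET1, MpCOP10 and MpDDB1 lay near the threshold and were lost on leaving out 15, 15 and 14 of the 24 single libraries. That for MpPRR was lost on leaving out 3 and without the 3 libraries rich in MpVg01240 (adjusted p = 0.097).

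Of the lists tested, those of heat shock genes and class III peroxidases were called lower on the second day, though not with an estimated correlation. All 4 genes of the chaperone HSP90 that were called fell (4 adjusted over the list alone). MpHSP90-2 (Mp2g04900) fell by 0.57 ± 0.08, MpHSP90-3 (Mp4g19750) fell by 0.56 ± 0.11, MpHSP90-4 (Mp5g15940) fell by 0.48 ± 0.06 and MpHSP90-1 fell by 0.39 ± 0.06. The 5 tested members of the list had a median of −0.48 (camera adjusted p = 4.6e-05, but adjusted p = 0.554 with an estimated correlation). Of 119 peroxidase genes 49 fell and 15 rose (64 adjusted over the list alone), with a median of −0.20 (camera adjusted p = 3.5e-05, but adjusted p = 0.851 with an estimated correlation). MpPOD68 (Mp5g03300) fell by 1.46 ± 0.12, and among those that rose were MpPOD26 by 1.13 ± 0.15 and MpPOD23 by 0.34 ± 0.06. The peroxidases also followed the main axis of variation within times, with a median loading of −0.08 on the log2 scale per 50 units of the axis. A Wilcoxon rank-sum test of their loadings against those of the other genes gave an adjusted p of 2.6e-04. That test takes genes as independent, so its p may be too small where members vary together.

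The remaining lists were not called as a whole between the days, which does not show that they stayed level. The largest medians in size were −0.29 for the cell cycle, −0.18 for tetrapyrrole synthesis and −0.16 for the core histones. Of 13 cell cycle genes 1 rose, the D-type cyclin gene MpCYCD_2 (Mp1g24670) by 0.34 ± 0.08. Another 4 fell, among them MpCYCD_1 (Mp8g17230), which fell by 0.36 ± 0.09 (9 called adjusted over the list alone, camera adjusted p = 0.110, and 0.851 with an estimated correlation, but 0.0196 without replicate 3 of 60 h and 0.0316 without replicate 2 of 42 h). Of 24 core histone genes 1 rose, MpH2B.1 by 0.35 ± 0.06, and 2 fell, among them MpH2A.W.2 (Mp3g00840), which fell by 0.22 ± 0.07 (2 adjusted over the list alone, camera adjusted p = 0.298, but 0.0252 without replicate 3 of 60 h). The call of MpH2A.W.2 was lost without the 3 libraries rich in MpVg01240 (adjusted p = 0.0665). The Calvin cycle list had 1 rise, MpRBCS (Mp4g09890) of the small Rubisco subunit by 0.41 ± 0.07. It had 1 fall, in MpFBA1 (Mp6g01550), which fell by 0.43 ± 0.09 (2 adjusted over the list alone, camera adjusted p = 0.933). Of the tetrapyrrole genes MpCHLI1/2-like fell by 0.24 ± 0.06 and MpCHLD fell by 0.18 ± 0.05 (2 adjusted over the list alone, camera adjusted p = 0.443). In the phenylpropanoid and flavonoid list 5 rose, among them MpPAL10 by 0.32 ± 0.05, and 5 fell (10 adjusted over the list alone, camera adjusted p = 0.799). Its median was 0.003, its mean −0.13 and the camera direction downward. The AP2/ERF list had 3 falls (2 adjusted over the list alone, camera adjusted p = 0.578), with MpERF4 (Mp2g11080), which fell by 0.46 ± 0.07. The R2R3-MYB list had 4 rises and 2 falls (6 adjusted over the list alone, camera adjusted p = 0.443), with MpR2R3-MYB4 (Mp3g02830) up by 0.40 ± 0.04. The auxin list had 2 rises, including MpTIR1 (Mp6g02750) by 0.21 ± 0.05, and 5 falls (7 adjusted over the list alone, camera adjusted p = 0.550). The reference list had 2 falls, including MpAPT (Mp3g25140), which fell by 0.31 ± 0.06 (2 adjusted over the list alone, camera adjusted p = 0.616). The reference list's median was 0.02, its mean −0.02 and the camera direction downward.

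Marker genes of other tissues that a young thallus can hold varied from gene to gene. Of the genes on the gemma cup list, MpKAR (Mp5g06550), MpGCAM1 (Mp6g04830) and MpCLE2 (Mp5g18050), 0 of 3 were rhythmic (0 adjusted over the list alone, Fisher's exact test adjusted p = 1.00) by edgeR, DESeq2 or limma-voom, and 0 at an unadjusted p under 0.05. How far each of them is confined to cups was not tested. Between the days MpKAR fell by 0.24 ± 0.05. MpGCAM1 was at 0.68 ± 0.36 (edgeR adjusted p = 0.15) and MpCLE2 at −0.14 ± 0.08 (1 called adjusted over the list alone, camera adjusted p = 0.539). The list's median was −0.14, its mean 0.10 and the camera direction downward. MpGCAM1, a MYB gene required for gemma cups, ranged from 3.41 to 26.03 CPM between the libraries of 48 h. The oil body markers had 1 of 4 rhythmic (1 adjusted over the list alone, Fisher's exact test adjusted p = 0.752), MpC1HDZ (Mp3g02320) with 1.49 fold and a peak at 21.2 h, which also fell by 0.23 ± 0.08 between the days (1 adjusted over the list alone, camera adjusted p = 0.799). The day call of MpC1HDZ (adjusted p = 0.0363) was lost on leaving out 12 of the 24 single libraries and by limma-voom (adjusted p = 0.0899). The rhizoid gene MpBHLH14 (Mp3g17930, the RSL1 homologue), at a mean of 22.9 CPM, fell by 0.27 ± 0.09 (adjusted p = 0.017). MpR2R3-MYB1 (Mp1g17210, synonym MpFGMYB), a regulator of female differentiation at a mean of 4.53 CPM in this male strain, rose by 0.87 ± 0.18 (adjusted p = 7.3e-04). With the strand setting unknown, these counts may come from the antisense strand of MpR2R3-MYB1. The sperm gene MpDUO1 (Mp1g13010) stayed at a mean of 0.575 CPM with no call.

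Times 24 h apart, at the same phase, still differed in many genes. The numbers were 2232 for 48 against 24 h (1191 higher and 1041 lower at the later time) and 1233 for 54 against 30 h (587 and 646). They were 1224 for 60 against 36 h (696 and 528) and 401 for 66 against 42 h (145 and 256), all by edgeR at an adjusted p under 0.05. Of the largest falls named above, MpPOD99 went from 17.2 ± 3.0 CPM (SD, n = 3) at 24 h to 10.7 ± 1.7 at 48 h and from 15.5 ± 2.4 at 42 h to 4.51 ± 0.81 at 66 h. Single libraries moved these counts. The 48 against 24 h contrast had 1465 genes without replicate 1 of 24 h, 1464 without replicate 2 of 24 h and 1150 without replicate 2 of 48 h. The 54 against 30 h contrast had 808 without replicate 1 of 30 h, 503 without replicate 3 of 30 h, 503 without replicate 1 of 54 h and 696 without replicate 2 of 54 h. The 60 against 36 h contrast had 357 and 575 without replicates 2 and 3 of 36 h, and 500 and 386 without replicates 1 and 2 of 60 h. The 66 against 42 h contrast had 192, 812 and 204 without replicates 1, 2 and 3 of 42 h, and 243 and 245 without replicates 1 and 2 of 66 h. Of the 812, 54.2% were higher at 66 h. For 66 against 42 h a fit of those times alone gave 60 genes, with 16.7% of them higher at 66 h against 36.2% of the 401.

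**Figure D3:**
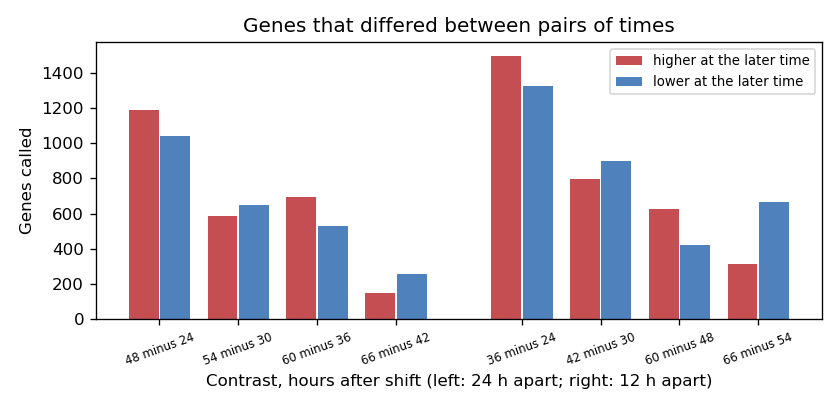
Number of genes called between pairs of times 24 h apart (left) and 12 h apart (right), in genes, with red bars for genes higher at the later time and blue bars for genes lower there. The 36 against 24 h contrast has the most genes (2828) and the 66 against 42 h contrast the fewest (401).

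The rhythms of the first and second day were called different in size or timing for 325 genes, and most rhythmic genes swung more on the first day. The share of such differences that the test finds was not simulated. Swings and peaks of each day were taken from its time means without a drift term, so a drift within a day enters them. MpBBX1 swung by 3.26 on the log2 scale on the first day and 2.25 on the second (SE 0.11 each), with peaks at 5.45 and 7.86 h (edgeR adjusted p of the difference 1.2e-04). MpPRR swung by 2.80 and 2.12 (SE 0.15 each) with peaks at 8.61 and 10.3 h (adjusted p = 0.0047), and MpDET1 by 1.60 and 1.27 (SE 0.10 each) with peaks at 0.945 and 2.91 h (adjusted p = 0.0271). MpLOX14 swung by 3.00 and 1.15 (SE 0.12 each, adjusted p = 8.5e-05). In all 325 genes differed, 197 of them rhythmic, and 275 of the 325 swung more on the first day. Over the 2700 rhythmic genes the median swing was 0.69 on the first day and 0.50 on the second, 75.3% swung more on the first day, and the peak lay a median of 1.35 h later on the second. Leaving out 1 library changed the count of 325 to 189, 170 and 170 without replicates 1, 2 and 3 of 24 h, 184 without replicate 3 of 30 h, 204 without replicate 3 of 36 h, 207 without replicate 3 of 42 h. It was 214 without replicate 2 of 48 h, 203 without replicate 3 of 54 h and 156 without replicate 1 of 60 h. It was 95 without the 3 libraries rich in MpVg01240 (91 of them among the 325) and 775 by DESeq2.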

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

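No test in this part was chosen only after its result was seen, except the fits without the 3 libraries rich in MpVg01240. The rhythms of the first and second day in constant light differed for 325 genes by the interaction of day and rhythm (edgeR adjusted p under 0.05), which is a difference between groups under the same contrast. Among named genes the B-box gene MpBBX1 (adjusted p = 1.23e-04) swung by 3.26 on the log2 scale on the first day and 2.25 on the second (SE 0.11 each), and its peak moved from 5.45 to 7.86 h. The clock gene MpPRR (adjusted p = 0.00467) swung by 2.80 and 2.12 with peaks at 8.61 and 10.3 h, and MpDET1 (adjusted p = 0.0271) by 1.60 and 1.27 with peaks at 0.945 and 2.91 h. MpPPR_73 (adjusted p = 0.00748) swung by 3.17 and 2.07 with peaks at 0.121 and 2.21 h, and the lipoxygenase gene MpLOX14 (adjusted p = 8.48e-05) by 3.00 and 1.15. MpPOD144 (adjusted p = 0.0274) swung by 1.65 and 0.64. The Rubisco gene MpRBCS (adjusted p = 0.0484) gave 0.99 and 0.10 and MpPOD99 (adjusted p = 0.0349) 0.42 and 1.41, but neither had a called rhythm (adjusted p = 0.342 and 0.131) and both changed largely one way, from a mean of 151 CPM at 24 h to 305 at 66 h for MpRBCS and from 17.2 to 4.51 for MpPOD99. None of 99 random orders of the 24 libraries gave as many as the 325 genes, with 7 as the highest. These orders also break up the rhythm and the change between the days. They therefore do not test the difference in rhythm by itself. Leaving out 1 library gave 156 to 368 genes, and 95 remained without the 3 libraries rich in MpVg01240, 91 of them among the 325.

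MpDET1, MpBBX1, MpPRR and MpPPR_73 all peaked later on the second day, as did 78.1% of the 2700 rhythmic genes, by a median of 1.35 ± 0.27 h (jackknife SE). Without the 4 libraries that stood farthest from the others of their time the median shift was still 1.24 h. These lay at 48 and 54 h, where a single library each was left, so the error of that value is not known. Over all libraries the median shift was 1.64 ± 0.34 h for genes with peaks near 0 h, 1.83 ± 0.31 h near 6 h, 0.865 ± 0.51 h near 12 h and 1.28 ± 0.37 h near 18 h. A fading drift of the same direction in all genes would shift opposite phases in opposite directions. The genes near 6 and 18 h both shifted later. For those near 12 h the direction stays open, since the shift less 2 SE is −0.153 h. Drifts went both ways, with 2639 genes up and 2349 down between the days. A single direction in all genes was thus not met, and the comparison cannot decide about a fading drift. A fading drift whose direction differs between phases was not tested and stays open. A period longer than 24 h may be behind the shift and stays open because of the genes near 12 h.

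MpBBX1, MpPRR, MpDET1, MpPPR_73, MpLOX14 and MpPOD144 all swung more on the first day, as did 75.3 ± 3.1% of the rhythmic genes (jackknife SE), with a median ratio of the second to the first day of 0.747 ± 0.03. A drift that adds to the difference between the times of the first day does not account for all of it: among the 553 genes whose change between the days went against that difference, 72.0% still swung more on the first day, and at the lowest 68.7% without replicate 1 of 48 h. Without the 4 libraries farthest out the share was still 68.8%, but 48 and 54 h then kept a single library each. The error of that share is therefore not known. A weakening of each plant's rhythm and a loss of step between cells or plants are hypotheses that the pooled tissue does not separate, and neither was tested.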

How the results depend on the processing

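Chosen after seeing the data were the fits without the 3 libraries rich in MpVg01240, with the main axis of variation within times as a covariate and with linear and day terms together. So were calls that hold with the linear term and with the day term, each in its own fit, and the alternatives for the gene lists other than the estimated correlation and the 0.01 threshold. The cause of the changes below was not tested unless stated. No called result of a named gene or a gene list was reversed in direction. For counts of genes the main direction did turn in the 66 against 42 h contrast. There 145 of 401 genes were higher at 66 h, and 440 of 812 without replicate 2 of 42 h. For named genes, 3728 of 3879 rhythm values and 3362 of 3447 day values kept their side of the threshold; 69 and 72 lost a call, from 20 and 10 results, and 82 and 13 gained one.

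The 2700 rhythmic genes became 1712 with a 22 h period (1659 shared), 4269 with day means as drift (2551 shared), 1009 with linear and day terms together (995 shared), 1460 by the rank test (1447 shared) and 1251 with a fitted change of at least 1.5 fold, a stricter criterion by construction. With linear and day terms together 275, 197, 419 and 118 genes peaked near 0, 6, 12 and 18 h, and with day means 1471 near 12 h and 843 near 18 h. Periods of 26 and 28 h gave 2916 (2515 shared) and 2757 (2212 shared). Other fits gave 2674 (RLE), 2806 (limma-voom) and 3106 (DESeq2) rhythmic genes. The difference in rhythm between the days had 775 genes by DESeq2 and 95 without the 3 libraries, which leaves fewer samples. The 66 against 42 h contrast had 680 genes by DESeq2 and 60 from those times alone; alone, 42 against 30 h gave 879, 60 against 48 h gave 450, 66 against 54 h gave 402 and 36 against 24 h gave 3520.

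Leaving out 1 library gave 2286 to 2852 rhythmic genes, 4662 to 5545 that differ between any times, 4422 to 5341 between the days and 156 to 368 with a different rhythm. The contrasts 24 h apart ranged over 1150 to 2111, 503 to 1012, 357 to 1696 and 192 to 812 genes, and those 12 h apart over 2158 to 2421, 941 to 1963, 580 to 1019 and 506 to 879. The adjusted p of rhythm ranged from 0.0319 to 0.0581 for tetrapyrrole synthesis, 0.0463 to 0.240 for the core clock and 0.0422 to 0.165 for auxin, and that of the day change from 0.0285 to 0.225 for the core clock, 0.0252 to 0.189 for light signalling, 0.0196 to 0.251 for the cell cycle and 0.0252 to 0.547 for core histones.

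With an estimated correlation the day change had an adjusted p of 0.554 for heat shock genes and 0.851 for peroxidases. Tetrapyrrole genes passed for rhythm at 0.0139 with calls under 0.01, 0.0210 with every gene of any count, 0.0427 without the 3 libraries and 0.0496 with a replicate block. They also passed at 0.0443 for calls that held with the linear term and with the day term, each in its own fit. No list was tested in the fit with linear and day terms together. Peroxidases were rhythmic less often than other genes with calls under 0.01 (0.0345), and core histones among genes of at least 5 CPM (0.0120). With every gene of any count the core clock (0.0490) and light signalling (0.0407) passed for the day change. The replicate block, whose numbers do not pair the libraries (median correlation of equal numbers 0.002), gave 2649 rhythmic genes, 4892 between the days and 263 with a different rhythm. The shallowest library held 14929708 counts, and 6160 genes had too few counts to be tested.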

Other observations

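Chosen after seeing the data were the tests of gene families by symbol and the comparison of the within-time axis with the day change. Genes of the BZIP transcription factors cycled more often than other genes: 10 of 13 were rhythmic (Fisher's exact test over 55 families, odds ratio 14.5, adjusted p = 4.7e-04). MpBZIP9 (Mp6g03920) was at 0.94 ± 0.15 on the log2 scale and a peak at 7.48 h, MpBZIP3 (Mp8g03820) at 0.74 ± 0.07 and 3.57 h, MpBZIP8 (Mp2g13330) at 0.61 ± 0.08, and MpBZIP1 (Mp1g16800) at 0.51 ± 0.07 and 22.1 h. Of the BHLH genes 16 of 37 were rhythmic (Fisher's exact test, odds ratio 3.32, adjusted p = 0.0141). The adjusted p of that test was 0.0676 for calls that held with the linear term and with the day term, each in its own fit. Fisher's test takes genes as independent, so the p of both families may be too small where members vary together. Autophagy genes rose between the days, 16 of 21 called and 0 fallen (camera adjusted p = 5.6e-08, but 0.454 with an estimated correlation), among them MpATG8b (Mp5g05930) by 0.67 ± 0.07 and MpATG8a (Mp1g21590) by 0.57 ± 0.07. Peroxin genes also rose, 8 of 17 (adjusted p = 0.0022, but 0.651 with an estimated correlation), with MpPEX11b (Mp1g26710) by 0.48 ± 0.07. Plasma membrane proton pump genes fell, 13 of 17 (adjusted p = 2.5e-05, but 0.395 with an estimated correlation), with MpHA13 (Mp3g07690), which fell by 0.71 ± 0.11, and MpHA2 (Mp3g21600), which fell by 0.57 ± 0.08. The pump genes also followed the main axis of variation within times (Wilcoxon rank-sum test, which takes genes as independent, adjusted p = 0.0182, median −0.13 per 50 units of the axis). Of the CSLD genes 6 of 10 fell, a cellulose synthase-like family (adjusted p = 0.0070, but 0.743 with an estimated correlation). All genes of this paragraph were chosen after their values were seen.

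Genes of late embryogenesis abundant (LEA-like) proteins differed widely between libraries of one time. Replicate 1 of 48 h had 41.7 CPM of the dehydrin gene MpDHN1 (Mp6g07540), chosen after its values were seen, and 26.03 CPM of MpGCAM1. Replicate 2 of 48 h had 0 counts of MpDHN1, which allows up to 0.156 CPM, and 3.41 CPM of MpGCAM1. Across the 24 libraries the deviations of MpGCAM1 and of the 51 LEA-like genes from their time means had a Pearson r of 0.898 (permutation p = 6.0e-05) and a Spearman rho of 0.906 (permutation p = 5.0e-05), and r was 0.894 without replicate 3 of 54 h and replicate 2 of 48 h. More gemma cups in some libraries may lie behind this. The other genes on the gemma cup list did not follow (r of 0.088 for MpKAR and −0.414 for MpCLE2). Whether those genes track the number of cups was not tested, so they do not decide the question. A label of a wrong phase is argued against, since the phase read from rhythmic genes lay within 1.90 h of the label in the 4 libraries farthest out. The phase is read modulo 24 h, so an exchange of libraries taken 24 h apart could not show in this test. Older or younger thalli stay open: across genes, which are not independent replicates, the axis and the day change had a Pearson r of 0.456 but a Spearman rho of −0.06, and the demand that both correlate was added after both were seen.

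For the counts over all libraries, none of 99 other orders of the 24 libraries, 100 with the real one, gave as many genes. The real counts were 2700 with a rhythm (highest other 9), 5307 that differ between any times (219) and 4988 between the days (0). A wholly random order of the libraries is thus argued against. The orders break up every difference between times at once. They cannot tell a rhythm from a step between the days, or from a difference shared by the libraries of a time. For pairs of times the 10 splits of 6 libraries are too few for a share under 0.05. The real and the highest other counts were 2232 and 0 for 48 against 24 h, 1233 and 0 for 54 against 30 h, 1224 and 0 for 60 against 36 h and 401 and 347 for 66 against 42 h. They were 2828 and 0 for 36 against 24 h, 1695 and 1 for 42 against 30 h, 1046 and 0 for 60 against 48 h and 976 and 0 for 66 against 54 h.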
